A study of Homo sapiens with 41 samples.

How the data were processed

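Messenger RNA was sequenced from CD8+ T cells of head and neck squamous cancer, 41 libraries in all. Per the labels' protocols, the tumour tissue was cut up and digested with enzymes, stained with antibodies to surface proteins that included CD3, CD4, CD8, CD14, CD19 and CD20, and CD8+ T cells were sorted directly into lysis reagent. Complementary DNA was made with the Smart-seq2 method, which amplifies full-length transcripts from small amounts of RNA. The labels give 1 group and name no batch, treatment or control tissue. They also do not state that the libraries come from separate donors. The names of the count columns carry a different HN code for each library, but whether a code stands for a donor is not stated. The p-values treat the libraries as independent samples.

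The authors deposited a single table of read counts per gene with 1 column per library, made with HTSeq on the hg19 genome per the submitters' processing notes. Tool versions, the aligner, the annotation and whether strand was used in counting are not given in the sources used here. The table had 23368 rows. In 28 of them the gene name had been turned into a calendar date, as spreadsheets do with some symbols, and these rows were left out because their genes could not be read. They held between 0.166% and 0.284% of a library's counts. This left 23340 gene rows. The gene annotation at hand was of a later build (GRCh38), so it served only to match older gene symbols, and positions are not printed.

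After these rows were removed, the libraries held from 1129183 to 10850185 counts, with a median of 6131513. Between 9757 and 17709 genes had at least 1 count, with a median of 14247. The 3 libraries with the fewest detected genes had 9757, 10000 and 10205, and the next had 11035. Among the 820 pairs of libraries 0 were identical, and the smallest chi-square per gene of any pair was 23.1, against a median of 79.4, so each library was counted as a separate sample. The lowest count of ITGAE in a library was 581 and that of PDCD1 was 98, which makes counting error small beside the spread between libraries.

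Before the data were examined, 23 gene lists with 315 genes were fixed, as were the tests, the alternatives and the rule for naming genes. Of these genes, 311 were found in the table. The 4 not matched were constant genes of the T cell receptor, which emptied the gamma-delta list. GPR56, PKM2 and C18orf1 are the older symbols of ADGRG1, PKM and LDLRAD4. Genes named are list members, taken within a list by smallest p, and, per fit, the 10 genes that rose and the 10 that fell with the smallest p among those past the threshold with a mean of at least 10 CPM, counts scaled to a common library total. Genes whose level is a trait of the donor (136 rows, among them Y-linked genes, receptor segments, the most polymorphic HLA genes, KIR genes other than KIR2DL4 and some genes with common deletions) were kept in library sizes and left out of every test and ranking. The innate receptor list was tested with KIR2DL4 and with 1 further member that is absent from some genomes.

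With 1 group there is no contrast between conditions, and libraries were never divided by an outcome. The relation of each gene to ITGAE (CD103) or PDCD1 (PD-1) was fitted with the marker's log2 CPM as a continuous term, in all 41 libraries, with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust, 2-sided), TMM factors, the default filterByExpr for 1 group and a prior count of 2. A slope is the log2 change of a gene per doubling of the marker, and its standard error (SE) is the slope divided by the square root of F. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. A joint model held both markers. The marker itself was never among the tested genes.

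Lists with at least 3 tested members (20 of the 23) were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and then with an estimated one, and with fry. A list score was the mean over members of log2(CPM + 1), each scaled to unit SD, without the marker it was set against. Scores were correlated with each marker by Pearson's r and Spearman's rho with 2-sided permutation tests of 100000 resamples, adjusted over the 20 lists, with 95% intervals from 10000 bootstrap resamples. The smallest p these permutations can give is 1e-05. Neither marker divided into 2 clusters (mclust 6.1.1; the BIC of 2 clusters was lower than that of 1, with differences of -7.23 for ITGAE and -5.17 for PDCD1). Variability was the tagwise against the trended dispersion of an intercept-only edgeR fit, without a test.

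Each fit was tested on simulated data made from the real means and library sizes of 9389 genes, of which 100 were given a slope of 0.5 and 100 a slope of 1. In the ITGAE fit 16% and 70% of these were recovered, in the PDCD1 fit 22% and 79%, and for the ITGAE slope of the joint model 13% and 58%. False calls made up 3.37%, 2.88% and 2.74% of all calls. Slopes of about 0.5 were therefore often missed at this number of libraries. The simulated genes were drawn independently of each other, and for the joint model they had no slope on PDCD1. Structure that genes share across the real libraries was thus absent, so the shares of false calls are not error rates of the real fits.

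The alternatives were other size factors (RLE), no low-count filter or at least 1 CPM in 21 libraries, DESeq2 1.42.0 and limma-voom, normal scores of the marker, a prior count of 0.5, the residency score in place of ITGAE, and fits without the 2 libraries farthest from the marker's median or the 4 smallest libraries. Others added covariates: depth and genes detected, the scores of 5 lists of other cell types, the label number, or the first principal component. The label number is the serial in the name of a library's count column, not the running number in the sample title. The number in the title was not used as a covariate. Both markers tended to be higher at low title numbers, which was not tested. PDCD1 stood at 8.68 log2 CPM in the library numbered 1 and at 5.96 in that numbered 41, and ITGAE at 10.3 and 8.86. The checkpoint score (0.646 and -0.631, without PDCD1) and the interferon score (0.767 and -0.180) tended the same way. Added after seeing the data were fits without the 3 libraries with the fewest genes detected and without the library with the highest share of MTRNR2L counts. Figures were drawn with matplotlib 3.10.9.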

Results

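The series asks, by its title, whether features of tissue-resident memory T cells go with the strength of the cytotoxic response in tumours, and the part used here holds CD8+ T cells sorted from head and neck squamous cancer. Read counts per gene were available for 41 libraries of 1 group, at 1129183 to 10850185 counts each. Values are TMM-scaled CPM given as mean ± SD over the 41 libraries unless stated otherwise.

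The libraries held abundant transcripts of CD8+ T cells, of several residency genes and of cytotoxic genes, with no other tissue to compare them with. PTPRC (CD45) stood at 2741 ± 573 CPM, CD8A at 2429 ± 563 and CD3D, a chain of the T cell receptor complex, at 1199 ± 327. Among residency genes, RGS1 reached 2468 ± 1042 CPM, CD69 1511 ± 548 and CXCR6, a chemokine receptor of tissue T cells, 640 ± 320. The cytotoxic genes GZMB (granzyme B) and GNLY (granulysin) were more uneven: GZMB averaged 1689 ± 1998 CPM with a range of 164 to 12936 and GNLY 1665 ± 1889, while GZMK stood at 1181 ± 658. CXCL13, a B cell attracting chemokine made by exhausted T cells in tumours, averaged 711 ± 669 CPM and ranged from 33.6 to 2654.

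Most markers of other cells had a low mean, and a few were high in single libraries. CD4 averaged 6.84 ± 12.5 CPM and had a count in 22 of the 41 libraries, and FOXP3 averaged 10.9 ± 12.2 CPM. The B cell gene MS4A1 averaged 45.1 CPM ± 44.0, the myeloid gene LYZ 58.3 ± 156, the keratin KRT6A 37.7 ± 133, the collagen COL1A2 9.62 ± 41.1 and the haemoglobin gene HBB 85.0 ± 140. The highest means in the B cell and myeloid lists were those of IGJ, which joins immunoglobulin chains, at 173 ± 479 CPM and S100A9, a neutrophil and monocyte gene, at 176 ± 523 with a maximum of 3365. The median member averaged 7.75 CPM in the B and plasma cell list, 14.7 in the myeloid list, 17.9 in the epithelial list, 3.97 in the stroma list, 8.87 in the CD4 and regulatory T cell list and 8.57 in the erythroid list, against 594 in the T cell identity list. Immediate early genes that tissue digestion can induce were high, with FOS at 1876 ± 947 CPM and DUSP1 at 1871 ± 873.

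**Figure D1:**
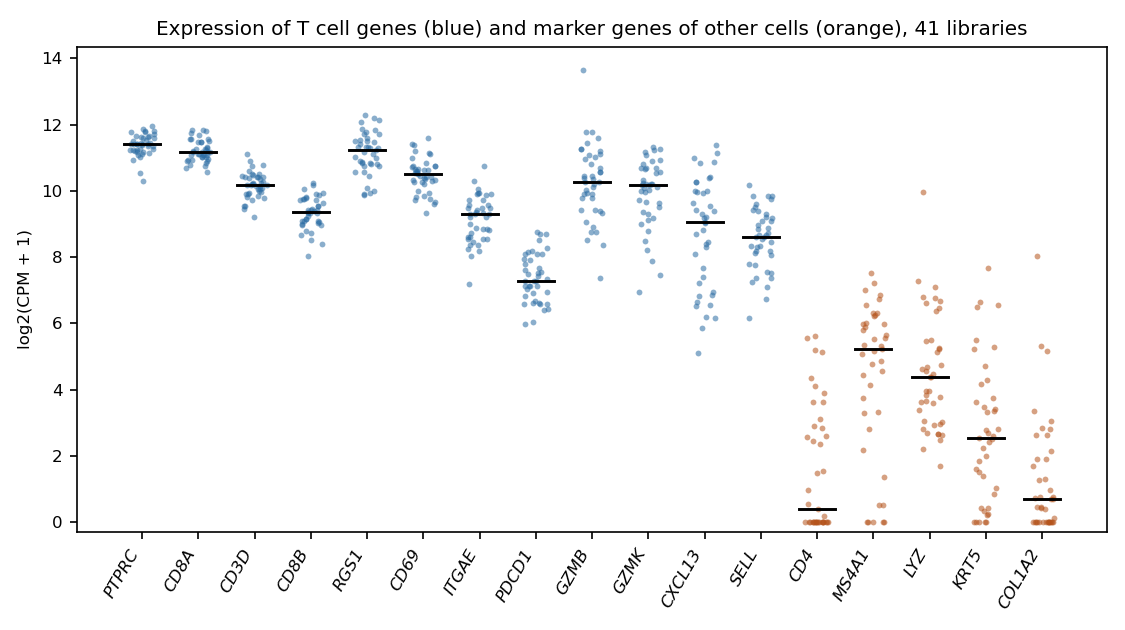
Expression (log2 of CPM + 1) of 12 T cell genes in blue and 5 marker genes of other cells in orange. Each point is 1 of the 41 libraries and the black bar is the median. CD8A lies between 1530 and 3656 CPM in every library, whereas CD4 has a median of 0.318 CPM.

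Among T cell programmes, interferon response and cell division genes varied most for their abundance, while T cell identity was even. The median biological coefficient of variation was 26.1% over the 13 T cell identity genes, 77.4% over the 20 interferon genes and 93.7% over the 22 proliferation genes, against 63.1% over 8686 genes. Relative to genes of the same abundance, the dispersion of interferon genes was 3.27 times the trend, the highest of the 20 lists, and that of proliferation genes 2.01 times. The 20 most variable genes included the interferon genes IFIT1, IFIT2, IFIT3, IFI27 and IFI44L, the heat shock genes HSPA1A and HSPA1B, whose near-identical sequences make the split of reads between them uncertain, and the T cell genes CXCL13, GNLY, KIR2DL4, CD101 and TNS3. They also included genes of other cells: HBB, S100A8, S100A9, KRT6A and the immunoglobulin-related IGLL5 (260 ± 686 CPM) and ELK2AP. IL8 had the highest ratio of all, 16.3, at 204 ± 448 CPM.

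ITGAE, which encodes the CD103 chain of an integrin that binds epithelial E-cadherin, averaged 631 ± 307 CPM and differed 11.7-fold between the lowest and the highest library. PDCD1, which encodes the inhibitory receptor PD-1, averaged 187 ± 98.5 CPM and differed 6.92-fold. The markers rose together across libraries, with Pearson's r = 0.467 (95% bootstrap interval 0.182 to 0.712, permutation p = 0.0019) and Spearman's rho = 0.467 (permutation p = 0.00225), a single relation with nothing to adjust for. Without the 2 libraries farthest from the ITGAE median r was 0.387.

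Libraries with more ITGAE had more of a small set of residency and exhaustion genes and less of the lymph node homing gene SELL. With each doubling of ITGAE, RBPJ, the nuclear effector of Notch signalling, rose by 0.69 ± 0.12 (log2 slope ± SE, n = 41), ENTPD1, which encodes the ectonucleotidase CD39, by 1.05 ± 0.19 and PHLDA1 by 0.82 ± 0.17. GPR25, an orphan receptor, rose by 1.75 ± 0.32, the transcription factor gene ETV1 by 1.36 ± 0.27, TNS3 by 2.02 ± 0.47 and ALOX5AP, needed for leukotriene synthesis, by 0.54 ± 0.12. SELL (L-selectin) fell by 0.78 ± 0.16, PLAC8 fell by 1.03 ± 0.21, FAM65B fell by 0.68 ± 0.12 and the adrenergic receptor gene ADRB2 fell by 0.73 ± 0.17.

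In the edgeR quasi-likelihood fit these belonged to 18 genes of 9388 with an adjusted p under 0.05, 7 of which rose and 11 fell, and 551 had an unadjusted p under 0.05. With limma-voom 25 genes passed, 18 rising and 7 falling, 10 of them among the 18, so the balance of directions depended on the tool. The adjusted p was 0.000778 for RBPJ, 0.00175 for ENTPD1 and 0.00815 for SELL. The other 7 genes that fell were MIR4461 (slope -0.81 ± 0.12) and 6 nuclear MTRNR2L genes, copies of the mitochondrial 16S ribosomal RNA gene whose reads cannot be assigned with certainty, MTRNR2L2 among them (slope -0.65 ± 0.10). These 7 rested on 1 library in which MTRNR2L genes took 18.5% of the counts, against a median of 2.60%. Without that library 9 genes passed, 7 rising and 2 falling, and 0 of those 7 did, while TNS3, PLAC8 and ADRB2 also lost their call and KRT86 gained one. TNS3 passed in 8 and ADRB2 in 6 of 15 alternatives. Without the 2 libraries farthest from the ITGAE median only RBPJ and ENTPD1 passed. The library rich in MTRNR2L counts is 1 of these 2, so the 2 checks are not separate. With the scores of 5 other cell types as covariates 0 genes passed, although all 11 genes other than the MTRNR2L genes and MIR4461 had an unadjusted p under 0.05.

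**Figure D2:**
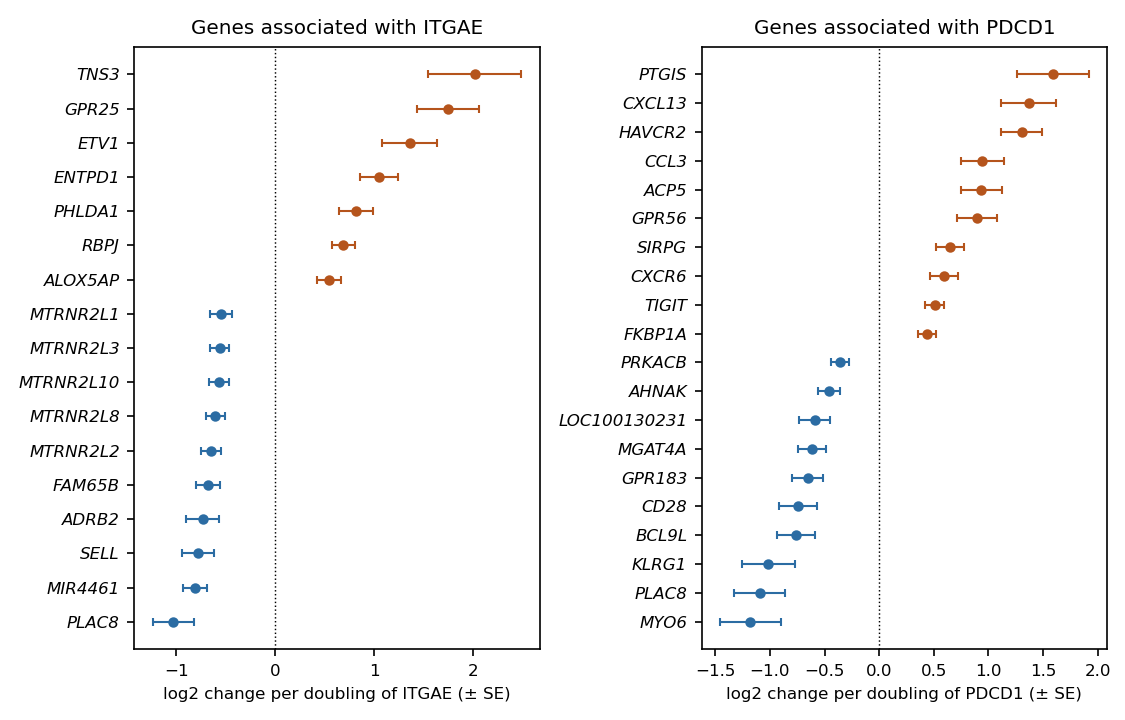
Slopes (log2 change per doubling of the marker, with bars of 1 SE, n = 41 libraries) of the named genes past the threshold in the ITGAE fit, left, and in the PDCD1 fit, right. Orange marks genes that rose and blue genes that fell. In the ITGAE panel 17 genes range from -1.03 for PLAC8 to 2.02 for TNS3, and the 6 blue points for MTRNR2L genes and MIR4461 rest on 1 library.

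By list, residency and checkpoint genes rose with ITGAE, and genes of recirculating and circulating T cells fell, as sets. Of 16 residency genes 1 rose (RBPJ) and 15 did not pass, but adjusted over the list alone 9 rose, among them MYO7A (0.89 ± 0.23), AMICA1 (0.39 ± 0.12) and ZNF683 (0.74 ± 0.22), which encodes the residency factor Hobit. CD69 had a slope of -0.11 ± 0.12, and 13 of the 16 slopes were positive. The camera test gave the residency list an adjusted p of 8.57e-09 (adjusted p = 0.00022 with an estimated correlation). Of 18 checkpoint genes 2 rose (ENTPD1 and PHLDA1) and 16 did not pass, and 12 rose adjusted over the list alone, including CXCL13 (0.96 ± 0.27) and TIGIT (0.37 ± 0.11). That list had a camera adjusted p of 3.53e-15 (adjusted p = 0.00022 with an estimated correlation). Of 15 recirculation and naive genes 1 fell (SELL) and 14 did not pass, 9 fell adjusted over the list alone, including LTB (-0.85 ± 0.25), TCF7 (-0.66 ± 0.20) and KLF3 (-0.99 ± 0.32), and 0 of 15 had a positive slope. Its camera adjusted p was 1.16e-11 (adjusted p = 0.00933 with an estimated correlation). Of 11 genes of circulating effector cells 0 passed over all genes and 3 fell adjusted over the list alone, CX3CR1 (-1.52 ± 0.47), KLRG1 (-0.81 ± 0.27) and PLEK (-0.49 ± 0.17), with a camera adjusted p of 2.71e-06 (adjusted p = 0.0128 with an estimated correlation).

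The cytotoxic genes did not all go the same way with ITGAE, although 14 of 18 slopes were positive. Of 18 tested, 0 passed over all genes and 1, GZMB (0.70 ± 0.22), rose adjusted over the list alone, while GZMK had a slope of -0.51 ± 0.20, RAB27A 0.23 ± 0.09 and IFNG 0.48 ± 0.20. The camera test with the preset correlation placed the list upward (adjusted p = 0.0103), and this was lost otherwise (adjusted p = 0.346 with an estimated correlation). The same held for the lists of proliferation (1.65e-09; adjusted p = 0.0951 with an estimated correlation), interferon response (1.32e-06; adjusted p = 0.346), costimulation (0.00759; adjusted p = 0.207), glycolysis (0.0145; adjusted p = 0.503) and innate receptors (0.00337; adjusted p = 0.159), all upward, with 0 members past the threshold over all genes. By smallest p these lists were led by TOP2A (0.50 ± 0.25), IFI27 (-0.66 ± 0.36), HLA-DRA (0.61 ± 0.19) and PGK1 (0.35 ± 0.12). Innate receptors had 5 members that rose adjusted over the list alone, such as KIR2DL4 (1.10 ± 0.29), KLRC1 (1.04 ± 0.29) and CD226 (0.72 ± 0.27), and 1 that fell, KLRF1.

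The other lists gave no camera call with ITGAE. Their adjusted p-values were 0.296 for T cell identity, 0.618 for lipid uptake, 0.607 for chemokines, 0.790 for TGF-beta response, 0.790 for type 17 genes, 0.0634 for dissociation stress, 0.222 for CD4 and regulatory T cells, 0.411 for B and plasma cells, 0.126 for myeloid cells and 0.618 for stroma. Members of the chemokine list had a median slope of -0.01 and a mean of 0.07, with the test upward. The epithelial list had 2 tested genes, too few for a set test: KRT6A (-0.97 ± 0.31) and PERP (-0.49 ± 0.22) fell adjusted over the list alone. The myeloid gene S100A9 (-0.81 ± 0.27) did so too, and HBB had a slope of -0.09 ± 0.60. Adjusted over the list alone, the dissociation stress gene JUNB (-0.48 ± 0.13) and the lipid gene CPT1A (-0.63 ± 0.19) also fell and the T cell gene CD7 (0.42 ± 0.12) rose.

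Across libraries, the residency score correlated with ITGAE at r = 0.653 (permutation p = 1e-05, the smallest possible, adjusted p = 1e-04; rho = 0.641, adjusted p = 2e-04) and the checkpoint score at r = 0.660 (permutation p = 1e-05, adjusted p = 1e-04; rho = 0.649, adjusted p = 3e-04). The recirculation score correlated at r = -0.529 (p = 0.00042, adjusted p = 0.0028; rho = -0.517, p = 0.00064, adjusted p = 0.00427) and the circulating effector score at r = -0.493 (p = 0.00092, adjusted p = 0.0046; rho = -0.413, p = 0.00806, adjusted p = 0.0403). Without the 2 libraries farthest from the ITGAE median r was 0.582, 0.571, -0.458 and -0.348 in the same order, and the last no longer passed. Given the other-cell scores and the number of genes detected, partial r was 0.548, 0.568, -0.490 and -0.490. The cytotoxicity score, which the title of the series would set beside residency, gave r = 0.252 (95% interval -0.0858 to 0.516, p = 0.113, adjusted p = 0.278) and rho = 0.248 (p = 0.118, adjusted p = 0.262), and r = 0.196 without the 2 farthest libraries, so a relation was not detected. This score is a mean transcript level within sorted CD8+ T cells. It does not measure how many such cells a tumour holds, so it is no test of the question in the title. The proliferation score missed the threshold at r = 0.366 (p = 0.0179, adjusted p = 0.0714). The share of MTRNR2L counts fell as ITGAE rose (r = -0.485, adjusted p = 0.0128 over 8 technical relations) but not by rank (rho = -0.252, adjusted p = 0.446), and 0 of the 4 other-cell scores passed.

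**Figure D3:**
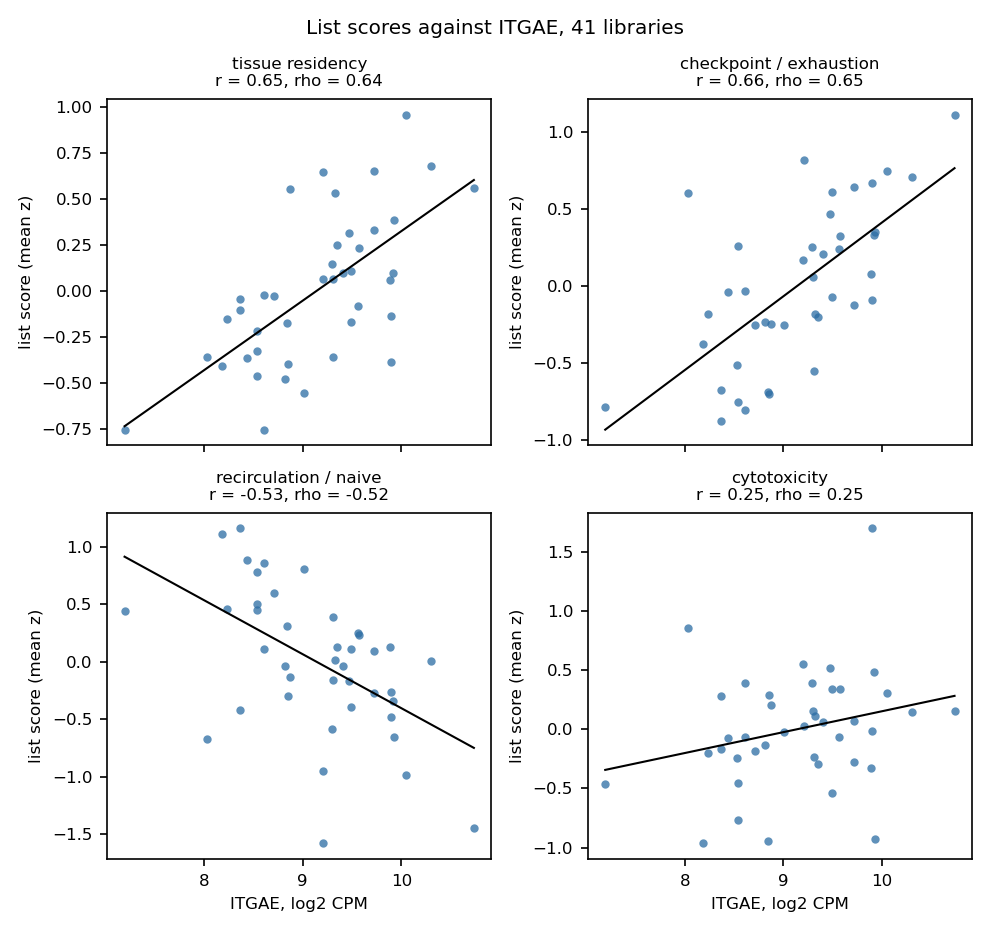
Scores of 4 gene lists (mean of scaled log2 values, vertical axes) against ITGAE (log2 CPM, horizontal axes) in 41 libraries, 1 point each, with least-squares lines. Residency (r = 0.65) and checkpoint genes (r = 0.66) rise, recirculation genes fall (r = -0.53), and the cytotoxicity score (r = 0.25) did not pass its test.

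Libraries with more PDCD1 had more of the inhibitory receptor genes HAVCR2, TIGIT and LAG3 and of the chemokine gene CXCL13, and less of CD28 and KLRG1. With each doubling of PDCD1, HAVCR2, which encodes the inhibitory receptor TIM-3, rose by 1.31 ± 0.19 (n = 41), CXCL13 by 1.37 ± 0.25, the inhibitory receptor gene TIGIT by 0.51 ± 0.09, SIRPG, a CD47-binding receptor, by 0.65 ± 0.13 and CCL3, an inflammatory chemokine with near-identical gene copies, by 0.94 ± 0.20. GPR56 rose by 0.90 ± 0.19, CXCR6 by 0.59 ± 0.13, ACP5 by 0.93 ± 0.19, PTGIS by 1.59 ± 0.33 and FKBP1A by 0.44 ± 0.09. The costimulatory receptor gene CD28 fell by 0.74 ± 0.18, GPR183, a receptor that guides lymphocytes in lymphoid tissue, fell by 0.66 ± 0.14 and KLRG1, an inhibitory receptor of circulating effector cells, fell by 1.01 ± 0.24. PLAC8 fell by 1.09 ± 0.23, MGAT4A fell by 0.62 ± 0.13, AHNAK fell by 0.46 ± 0.10, BCL9L fell by 0.76 ± 0.17, PRKACB fell by 0.35 ± 0.08, MYO6 fell by 1.18 ± 0.28 and LOC100130231 fell by 0.59 ± 0.14.

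The edgeR quasi-likelihood fit called 73 of 9388 genes, 48 rising and 25 falling, and 1106 had an unadjusted p under 0.05. The adjusted p was 7.31e-05 for HAVCR2, 0.00451 for TIGIT and 0.00608 for CXCL13. Without the 3 libraries with the fewest genes detected 171 genes passed, 62 of which were among the 73. PHLDA1 was the 1 gene that rose with both markers, where 0.0358 would be shared by independent lists, and 3 genes fell with both (PLAC8, MTRNR2L2 and MIR4461, against 0.0293). Without the library rich in MTRNR2L counts PHLDA1 still rose with both and 0 genes fell with both. Both fits use the same libraries and the markers correlate, so part of this overlap follows from that.

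By list, 8 of 17 checkpoint genes rose with PDCD1 and 9 did not pass, and 12 rose adjusted over the list alone. Besides those above they included LAYN (1.38 ± 0.29), LAG3 (0.61 ± 0.14) and TOX (0.48 ± 0.11), which encodes a transcription factor of exhausted T cells. The camera adjusted p of the list was 4.66e-13 (adjusted p = 0.000219 with an estimated correlation), and it was the only list of 20 to keep its call with an estimated correlation. With fry 7 of the 8 lists called by camera kept their call, all but cytotoxicity. Of 22 proliferation genes 2 rose, MCM5 (0.71 ± 0.17) and STMN1 (0.64 ± 0.17), and 17 rose adjusted over the list alone (camera adjusted p = 4.72e-12; adjusted p = 0.0787 with an estimated correlation). Of 20 interferon genes 0 passed over all genes and 12 rose adjusted over the list alone, such as IFI6 (0.87 ± 0.23), OASL (0.53 ± 0.15) and MX1 (0.79 ± 0.22), and 20 of 20 slopes were positive (camera adjusted p = 1.18e-14; adjusted p = 0.0876 with an estimated correlation). Of 13 glycolysis genes 4 rose, GAPDH (0.51 ± 0.11), ENO1 (0.46 ± 0.11), TPI1 (0.53 ± 0.13) and PGK1 (0.44 ± 0.11), and 9 rose adjusted over the list alone (camera adjusted p = 1.24e-05; adjusted p = 0.166 with an estimated correlation).

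Of 18 cytotoxic genes 1 rose with PDCD1, the perforin gene PRF1 (0.57 ± 0.14), 17 did not pass, and 7 rose adjusted over the list alone, including GZMB (0.69 ± 0.22) and GNLY (0.76 ± 0.27). The camera adjusted p was 0.0178 (adjusted p = 0.435 with an estimated correlation). Of 12 costimulation genes 1 rose, TNFRSF9 (0.73 ± 0.16), the gene of 4-1BB, and 7 rose adjusted over the list alone (camera adjusted p = 0.000386; adjusted p = 0.0876 with an estimated correlation). Of 17 residency genes 1 rose, CXCR6, and 4 rose adjusted over the list alone (camera adjusted p = 0.00071; adjusted p = 0.0876 with an estimated correlation). Of 15 recirculation genes 2 fell, CD28 and KLF3 (-1.11 ± 0.27), and 5 fell adjusted over the list alone (camera adjusted p = 4.98e-06; adjusted p = 0.0915 with an estimated correlation). The 11 circulating effector genes went both ways, GPR56 up and KLRG1 down, with a camera adjusted p of 0.128.

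The remaining lists gave no camera call with PDCD1. The adjusted p was 0.124 for T cell identity, in which CD7 rose (0.48 ± 0.11), 0.195 for chemokines, in which CCL3 rose, 0.481 for lipid uptake, 0.335 for TGF-beta response, 0.948 for type 17 genes, 0.433 for innate receptors, 0.0678 for dissociation stress, 0.948 for CD4 and regulatory T cells, 0.948 for B and plasma cells, 0.195 for myeloid cells and 0.676 for stroma. The direction of the test and the median slope differed in sign for the type 17, the CD4 and regulatory T cell and the stroma lists, and the mean and the median did for B and plasma cells. The epithelial genes PERP (-0.70 ± 0.27) and KRT6A (-1.15 ± 0.53) fell adjusted over the list alone, and HBB had a slope of -0.08 ± 0.57.

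Across libraries, 7 of 20 list scores correlated with PDCD1 after adjustment. The checkpoint score led with r = 0.750 (permutation p = 1e-05, the smallest possible, adjusted p = 2e-04; rho = 0.767, p = 1e-05, adjusted p = 2e-04), followed by proliferation with r = 0.514 (p = 0.00064, adjusted p = 0.0064; rho = 0.546, p = 0.00029, adjusted p = 0.0029). Recirculation had r = -0.471 (p = 0.00193; rho = -0.487, p = 0.00136), costimulation r = 0.469 (p = 0.00194; rho = 0.492, p = 0.00141) and interferon response r = 0.466 (p = 0.00234; rho = 0.502, p = 0.00101), each with an adjusted p of 0.00936 for r and 0.00564 for rho. Residency had r = 0.444 (p = 0.00374, adjusted p = 0.0125; rho = 0.425, p = 0.00602, adjusted p = 0.0201) and glycolysis r = 0.391 (p = 0.0111, adjusted p = 0.0318; rho = 0.352, p = 0.0242, adjusted p = 0.0605). Without the 2 libraries farthest from the PDCD1 median r was 0.818 for checkpoint, 0.631 for proliferation, -0.448 for recirculation, 0.498 for costimulation, 0.501 for interferon response, 0.502 for residency and 0.495 for glycolysis. Given the other-cell scores and the genes detected, the partial r of residency was 0.310 and no longer passed (adjusted p = 0.122). Without the 4 smallest libraries residency (r = 0.362) and glycolysis (r = 0.332) no longer passed, nor did glycolysis with unscaled members (r = 0.350). The cytotoxicity score did not pass, at r = 0.268 (95% interval -0.0116 to 0.497, p = 0.0909, adjusted p = 0.186) and rho = 0.259 (p = 0.104, adjusted p = 0.190), and r was 0.310 without the 2 farthest libraries. The MTRNR2L share fell with PDCD1 by rank (rho = -0.483, adjusted p = 0.011) but not by Pearson's r (-0.275, adjusted p = 0.309).

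**Figure D4:**
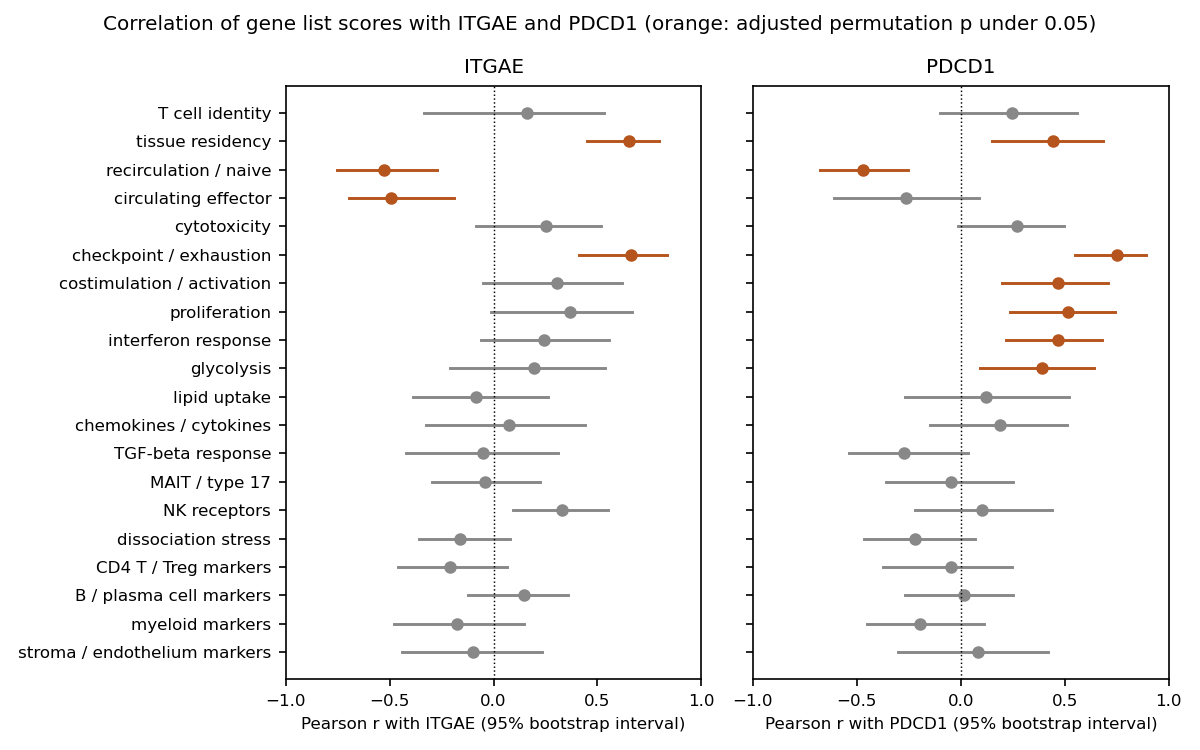
Pearson's r of 20 list scores with ITGAE, left, and PDCD1, right, over 41 libraries, with 95% bootstrap intervals. Orange marks an adjusted permutation p under 0.05, which 4 scores reached with ITGAE and 7 with PDCD1, and the scores of other cell types and of cytotoxicity are grey in both panels.

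With both markers in 1 model, HAVCR2, TIGIT and CXCL13 still passed for PDCD1, LAG3, LAYN and TOX did not, and RBPJ passed for ITGAE, as it did in 7 of 15 alternatives. At a fixed PDCD1, RBPJ rose by 0.67 ± 0.13 per doubling of ITGAE (edgeR adjusted p = 0.0250). The other of the 2 genes past the threshold was MTRNR2L6 (slope -1.13 ± 0.21), which the naming rule leaves out for its low mean of 7.32 CPM and which was chosen for naming after the values were seen. ENTPD1 (0.93 ± 0.21, adjusted p = 0.0706) and SELL (-0.79 ± 0.17, adjusted p = 0.0650) narrowly missed it, and 396 of 9387 genes had an unadjusted p under 0.05. Without the library with the most MTRNR2L counts 0 genes passed.

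At a fixed ITGAE, 16 genes passed for PDCD1, 13 rising and 3 falling. HAVCR2 rose by 1.25 ± 0.20 (edgeR adjusted p = 0.000777), CXCL13 by 1.23 ± 0.23, GPR56 by 1.13 ± 0.22, SIRPG by 0.64 ± 0.14 and FKBP1A by 0.46 ± 0.10. The interferon-induced genes BST2 (0.64 ± 0.14) and LY6E (0.67 ± 0.14) rose as well, as did CNP (0.78 ± 0.18), TADA3 (0.64 ± 0.14) and GET4 (0.69 ± 0.15). MIAT, a long noncoding RNA, fell by 0.83 ± 0.19, MGAT4A fell by 0.69 ± 0.15 and PRKACB fell by 0.42 ± 0.09. Without the 2 libraries farthest from the ITGAE median 3 genes passed, HAVCR2, CXCL13 and GPR56, and without the 3 libraries with the fewest genes detected 29 did, only 8 of them among the 16, with TIGIT, FKBP1A, MIAT, MGAT4A, GET4 and TADA3 among those lost. LAG3 was among those gained there, so the split between TIGIT and LAG3 turned on these 3 libraries. GET4 passed in 7 of 14 alternatives, BST2 and TADA3 in 8 of 15 and CNP in 9 of 15. Whether a gene's slopes on the markers differ from each other was not tested.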

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

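The fits without the 3 libraries with the fewest genes detected and without the library with the most MTRNR2L counts were chosen after seeing the data. No paired analysis was possible because there is 1 group. The genes that passed kept the sign of their slope in every setting, 18 of 18 for ITGAE (17 of the 17 tested with the residency score in its place, which leaves out RBPJ) and 73 of 73 for PDCD1, and 0 results reversed. The count of 18 genes with ITGAE became 784 without a low-count filter, 45 with DESeq2, 2 without the 2 libraries farthest from the median, 0 with other-cell scores, 49 with the residency score (8 rising, 41 falling) and 9 without the library rich in MTRNR2L. The 73 genes with PDCD1 became 841 without a filter, 194 with DESeq2, 143 without the 4 smallest libraries and 171 without the 3 libraries with the fewest genes. Of the unfiltered calls 725 and 667 were genes that the filter removes, with a median of 4 libraries holding any count. For ITGAE given PDCD1, 2 genes became 268 without a filter, 12 with DESeq2, 4 with limma-voom, 1 with normal scores, and 0 with the filter of 1 CPM in 21 libraries, without the 4 smallest libraries, with other-cell scores, with the label number, without the 3 libraries with the fewest genes and without the MTRNR2L library. For PDCD1 given ITGAE, 16 became 280, 89 and 6 in the first 3 of these, 3 without the 2 farthest libraries, 6 with depth covariates, 3 with other-cell scores, 7 with the label number and 29 without the 3 libraries with the fewest genes. Lists called by camera went from 10 to 4 with an estimated correlation and 4 with fry for ITGAE. For PDCD1 they went from 8 to 1 with an estimated correlation but to 7 with fry. With other-cell scores the median absolute slope of the 11 genes called for ITGAE other than MTRNR2L and MIR4461 stayed at 0.83, against 0.82, while the SE grew. For the other changes the cause was not tested, apart from the unfiltered genes and the MTRNR2L library. The cytotoxicity score stayed short of the threshold in all 10 alternatives, at r = 0.196 to 0.294 with ITGAE and 0.249 to 0.311 with PDCD1. HAVCR2, TIGIT and CXCL13 passed for PDCD1 in all 15 alternatives, and RBPJ and ENTPD1 for ITGAE in 14 of 15 that kept ITGAE as the marker. Of the 20 most variable genes 17 were again among the top 20 without the 4 smallest libraries. In the simulation slopes of 0.5 were mostly missed. Some real genes with smaller slopes still passed, such as PRKACB (-0.35 ± 0.08) and FKBP1A (0.44 ± 0.09) in the PDCD1 fit.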

Other observations

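Among the tests below, those of other genes used as the marker without the 3 libraries with the fewest genes detected, those of the checkpoint list with ITGAE, and the fit without the library rich in MTRNR2L, were chosen after the results were seen.

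List scores, taken without ITGAE and PDCD1 as members, also moved with each other, and whether they do so at a fixed level of either marker was not tested. Of 190 pairs of scores, proliferation and glycolysis had the highest r and rho over all libraries, though not without 2 libraries or by partial r (Pearson's r = 0.783, permutation p = 1e-05, the smallest possible, adjusted p = 0.000173; rho = 0.744, adjusted p = 0.000238; r = 0.696 without the 2 libraries farthest from the median of the first score). Cytotoxicity went with glycolysis (r = 0.747; rho = 0.662; 0.636 without the 2) and with chemokines (r = 0.717; rho = 0.670; 0.654 without the 2), each with a permutation p of 1e-05 for r and rho and adjusted p-values of 0.000173 and 0.000238. Glycolysis genes, such as GAPDH and ENO1, were thus high as a set where the cytotoxic genes, such as GZMB and PRF1, were high as a set. Recirculation went against checkpoint (r = -0.614, p = 2e-05, adjusted p = 0.000253; rho = -0.611, p = 4e-05, adjusted p = 0.000543; -0.590 without the 2) and against cytotoxicity (r = -0.480, p = 0.00154, adjusted p = 0.0104; rho = -0.617, p = 4e-05, adjusted p = 0.000543; -0.474 without the 2). Residency and cytotoxicity were not among the pairs past the threshold.

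Granzymes B and K went opposite ways with ITGAE. As a hypothesis, CD103-rich libraries may hold cells that express GZMB in place of GZMK: log2 GZMB minus log2 GZMK correlated with log2 ITGAE at r = 0.5845 (95% interval 0.331 to 0.768, permutation p = 5e-05) and rho = 0.531 (permutation p = 0.00044), with r = 0.538 without the 2 farthest libraries. GZMB alone gave r = 0.434 (p = 0.00493; rho = 0.427, p = 0.00579) and GZMK alone r = -0.514 (p = 0.00065; rho = -0.384, p = 0.0136), p-values that are not adjusted over these 3 relations. The pair was picked from the ITGAE fit of the same libraries, so the difference restates those slopes and is no independent support. In the fit over all genes neither passed (edgeR adjusted p = 0.275 for GZMB and 0.607 for GZMK). Bulk counts do not tell a change within cells from a change in the mix of cells.

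A further hypothesis, which the same libraries gave rise to, was that cycling cells may be more frequent where checkpoint genes are high. The proliferation and checkpoint scores, without PDCD1 and ITGAE, correlated at r = 0.7116 (permutation p = 1e-05, the smallest possible, adjusted p = 0.000173 over the 190 pairs; rho = 0.705, adjusted p = 0.000238) and at 0.673 without the 2 farthest libraries, and the partial r given other-cell scores and genes detected was 0.670 (permutation p = 2e-05). This is 1 of the 190 pairs above and no separate test of the hypothesis, and neither score counts cells.

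The 73 genes called for PDCD1 formed the clearest pattern. Of 100 orders of the PDCD1 values, the real one included, 1 gave as many genes, and the highest of the others gave 1, so chance alone is an unlikely source. Neither the other-cell scores nor depth took up the slopes of the 73 genes. With the other-cell scores as covariates the median ratio to the slopes without them was 1.016 (44 still passed). With depth and genes detected it was 0.9973 (62 still passed). The MTRNR2L share fell with PDCD1 by rank (rho = -0.483, permutation test, adjusted p = 0.011). It was not used as a covariate, so what goes with it stays open. The other-cell scores rest mostly on genes of low level, so RNA of other cells that they miss stays open. The count itself is not special to PDCD1, since 79 of 100 other genes of like level and spread called at least as many in limma-trend (91 for PDCD1, a median of 750 and up to 2155 for the others), and 57 of 100 did without the 3 libraries with the fewest genes (251 for PDCD1), which points to a structure among the libraries that many genes share. With the first principal component as a covariate 73 genes passed, 67 of them the same. That fit takes out only 1 axis, whose relation to PDCD1 was not measured, so it cannot exclude such a structure. For the checkpoint list, 0 of 100 other genes gave a mean t as high as PDCD1 did (3.08 above all genes, against 2.95 at most). PDCD1 is itself a member of that list by design, while the other genes were matched only for level and spread. This comparison therefore cannot decide between a structure shared by the libraries and a shared exhaustion programme, for which no biological contrast was available. The order of the sample titles was not tested either, although PDCD1, ITGAE and the checkpoint and interferon scores all tended to follow it.

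For the 18 genes called for ITGAE, 1 of 100 orders gave as many and the highest other gave 8. The orders kept the library rich in MTRNR2L counts, on which 7 of the 11 falling genes rest, and were not repeated without it. For the 7 rising genes, of which the other orders gave 1 at most, chance alone is an unlikely source. With the other-cell scores, the slopes of the 11 genes other than MTRNR2L and MIR4461 had a median ratio of 1.016 (quartiles 0.940 and 1.07). This argues against the RNA that these scores measure as the whole cause. Yet the calls ended: the median absolute slope was 0.82 before and 0.83 after, while the SE grew by a median factor of 1.25 and the smallest edgeR adjusted p became 0.0634. The scores rest mostly on genes of low level, so RNA of other cells that they miss stays open. With the first principal component as a covariate 19 genes passed, 18 of them the same, but that fit takes out only 1 axis, whose relation to ITGAE was not measured. A structure shared by the libraries stays open, because 48 of 59 other genes called at least as many (7 for ITGAE in limma-trend, a median of 158 and up to 2136 for the others) and 33 of 44 did without the 3 libraries with the fewest genes (12 for ITGAE). It stays open for the recirculation list too, to which 4 of 59 other genes gave a mean t as low as ITGAE did (-2.29, against -3.03 at the lowest), and for the checkpoint list, to which 2 of 59 gave a mean t as high (2.47, against 2.83 at the highest) and 5 of 44 did without the 3 libraries (2.51, against 2.72). For the 2 genes called for ITGAE at a fixed PDCD1, 5 of 100 orders gave as many and the highest other gave 8, so chance is not excluded. The order of the sample titles, which ITGAE tended to follow as well, was not tested for any of these genes.

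The fall of 6 MTRNR2L genes and MIR4461 with ITGAE rested largely on a single library. Without the library in which MTRNR2L genes took 18.5% of the counts, the median ratio of their slopes to the full ones was 0.2745 and 0 of 7 passed, the median absolute slope going from 0.60 to 0.16. Depth and the number of genes detected are argued against, since with both as covariates the ratio was 1.005 and 7 of 7 passed. That library also had the lowest ITGAE of all (146 CPM), the lowest T cell identity score (-1.16), the highest KRT5 (204 CPM) and the highest COL1A2 (262 CPM). RNA of other cells therefore stays open as a source, and no biological explanation was tested.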
